A study of Homo sapiens with 2 samples.

How the data were processed

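RNA from parental and from taxol-resistant MDA-MB-231 breast cancer cells was measured on 2 Agilent 2-colour whole-genome arrays, both on 1 slide. Per the labels, total RNA was isolated with a Qiagen RNeasy Mini kit and labelled with an Agilent low-input kit, and the second array repeats the first with the dyes reversed. Per the file headers, the scans were read with Agilent Feature Extraction 10.5.1.1, and the grid names the genome build hg18. The deposited scanner files hold, per the file headers, the median pixel intensity of each spot and of its local background in each dye. They also hold processed signals, which are intensity values already background-subtracted and dye-normalised by the software. The deposited log10 ratio is that of the processed Cy5 signal over the processed Cy3 signal. It matched the signals within 0.001 except at 8676 spots on one array and 8449 on the other, where it was set to 0. The deposited p-value of each spot comes, per the file headers, from the software's error model for that array alone. The series table, also deposited by the authors, held log10 ratios of Cy5 over Cy3 that differed from the scanner files by less than 0.005, were not turned for the dye reversal and had a median of 0 in each column.

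The arrays carried 45015 spots, of which 1639 were controls. Outlier flags marked 124 and 155 of the 43376 other spots, and no spot was saturated. Well-above-background shares were 71.5% (Cy3, parental) and 67.7% (Cy5, resistant) on the first array and 68.3% (Cy3, resistant) and 67.6% (Cy5, parental) on the second. The median signal lay between 136 and 177, over a median local background of 25 to 27 in Cy3 and 54 in Cy5. The number of arrays limits the precision. Since both arrays lay on 1 slide, no batch could be tested.

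Background was corrected with normexp (offset 50) in limma 3.58.1 under R 4.3.3, on median signal and background median. The median stood in for the mean signal that had been planned, as the files used here hold no mean signal. Arrays were then normalised within each array by loess, with control and outlier spots at weight 0. Ratios were turned to resistant over parental from the dyes in the labels and averaged over the arrays, as a technical dye swap. The labels do not say outright that both arrays used the same extracts. Spots of a probe were averaged, and a gene took its probe of highest mean intensity. Probes were named through their RefSeq accessions, without versions, in a table of the GRCh38.p14 assembly, used only for names, chromosomes and gene order. Of 41000 probes, 23675 matched a gene symbol, including 23478 of 24692 with a RefSeq mRNA accession, and 17325 stayed unnamed. This gave 16413 genes, 5673 of them with over 1 probe.

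A gene was measured if over 50% of its probe's spots were well above background in the brighter RNA on both arrays. It was called higher or lower if its ratio was at least 2-fold in that direction on both arrays. Where the dimmer RNA was not well above background on either array, the fold is a lower bound. It sets the brighter RNA's mean against, per array, the higher of the lowest signal among probes well above background and the probe's own signal, from single-channel values after loess and Aquantile scaling. Genes were named in the text by a rule set before the data were examined. It took ABCB1, the 12 highest and 12 lowest called genes that were well above background in both RNAs, up to 6 bounded genes in each direction, and up to 4 called members of each list by size. For a list with no called member it allowed up to 2 members as values. Only genes with a symbol were named, and 1 gene that the rule takes is not reported here.

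The 31 gene lists were fixed before the data were examined. The median of each was placed among 10000 random lists of the same size drawn from 20 bins of mean intensity, and lists in the outer 0.5% at either end were said to stand apart. For the chromosome regions, the running median over 15 genes was compared with the 95th percentile of maxima, and the matching bound for minima, of 1000 shuffles of gene order. Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9 was used.

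The steps were tested on simulated arrays of 12755 genes for this comparison. Of 50 genes per size, 0 were called at a simulated 1.5-fold, 33 at 2.5-fold, 46 at 4-fold and 47 at 8-fold, and 0 of 12505 unchanged genes were called. The simulated noise was normal, of a chosen size and without variation between cultures. The count of unchanged genes called is therefore no false-call rate for the real arrays. Of 200 unchanged lists, 3 stood apart. A list of genes shifted by 0.3 log2 stood at percentile 100, the raised block of 20 genes was found and 0 regions were found elsewhere. The block was shifted by more than the median of any region found in the real arrays. Mean log2 ratios of measured genes in the real arrays had an SD of 0.41, while most simulated genes were unchanged. The list and region results therefore give no rate of finding weaker shifts in the real arrays. The offset draws ratios of dim probes towards 0, so the median log2 ratio recovered at 8-fold was 2.80.

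Alternatives were no background subtraction, the software's processed signals, median centring, the series table, the median over probes, other filters on dim probes, each array alone, other size rules, the error model's p-value, list means, unmatched random lists and a longer window. A smaller normexp offset of 10 and lists without genes of the chromosome regions were added after the data had been seen. Leaving out saturated spots was not run, as none was saturated.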

Results

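Gene expression was compared between MDA-MB-231 cells, an established line of triple-negative breast cancer cells, and a derivative of the same line that is resistant to taxol, a drug that stabilises microtubules. The sample title names P-gp (P-glycoprotein), the drug efflux pump encoded by ABCB1. Total RNA of the resistant and of the parental cells was hybridised together on 2 whole-genome arrays of 45015 spots each. On 1 array the resistant RNA carried the red dye Cy5 and the parental RNA the green dye Cy3, and on the other array the dyes were reversed. The labels describe a dye reversal of 2 RNAs and do not name separate cultures, so the arrays were counted as 1 replicate of each RNA. No test between conditions was therefore possible, and genes were called by a fixed rule of size. Between 67.6% and 71.5% of the non-control spots were well above background, depending on array and dye. After matching to gene symbols, 12413 genes were measured, that is, well above background in the brighter RNA on both arrays. All ratios are resistant over parental. As the technical error, a gene's ratio on an array deviated from its mean over both dye orientations by 0.14 (SD over measured genes, log2 scale).

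The first comparison asked how ABCB1 RNA differed between the cells. Among called genes well above background in both RNAs, ABCB1 had the highest mean log2 ratio, at 5.41, which corresponds to 42.4-fold more signal in the resistant cells. The log2 ratio was 6.37 (82.7-fold) with resistant RNA in Cy5 and 4.44 (21.8-fold) with resistant RNA in Cy3, so the direction was shared and the size was not. The single ABCB1 probe was spotted 10 times on each array. In the deposited processed intensities the parental RNA gave 112 ± 7.9 (SD over 10 spots) on the array with resistant RNA in Cy5 and 483 ± 13.7 on the other, while the resistant RNA gave 15315 ± 381 and 12343 ± 154. Spots of 1 array are technical repeats, and all 10 were well above background in the parental RNA on each array. Among 15 measured drug efflux transporters of the ABC family and related genes, ABCB1 was called higher, the other 14 were not called, and the list median was 0.02.

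Several genes near ABCB1 on chromosome 7 were also higher. TMEM243, a transmembrane protein gene, had a log2 ratio of 4.63 (24.8-fold), CROT, a peroxisomal carnitine acyltransferase, 3.51 (11.4-fold), and DMTF1, a cyclin D-binding transcription factor, 3.05 (8.29-fold). GRM3, a glutamate receptor gene, was at least 2.95-fold higher, since its parental signal was not well above background on either array. Of 33 measured genes on the list of ABCB1 neighbours, 5 were called higher and none lower, and 19 were above 0 on both arrays. The list median was 0.34, at percentile 100 of random lists matched on intensity. In gene order the higher values ran from SEMA3D to CDK14, with SEMA3A at -0.92 on one side and FZD1 at -0.02 on the other. These 4 flanking genes were named after their values were seen.

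**Figure D1:**
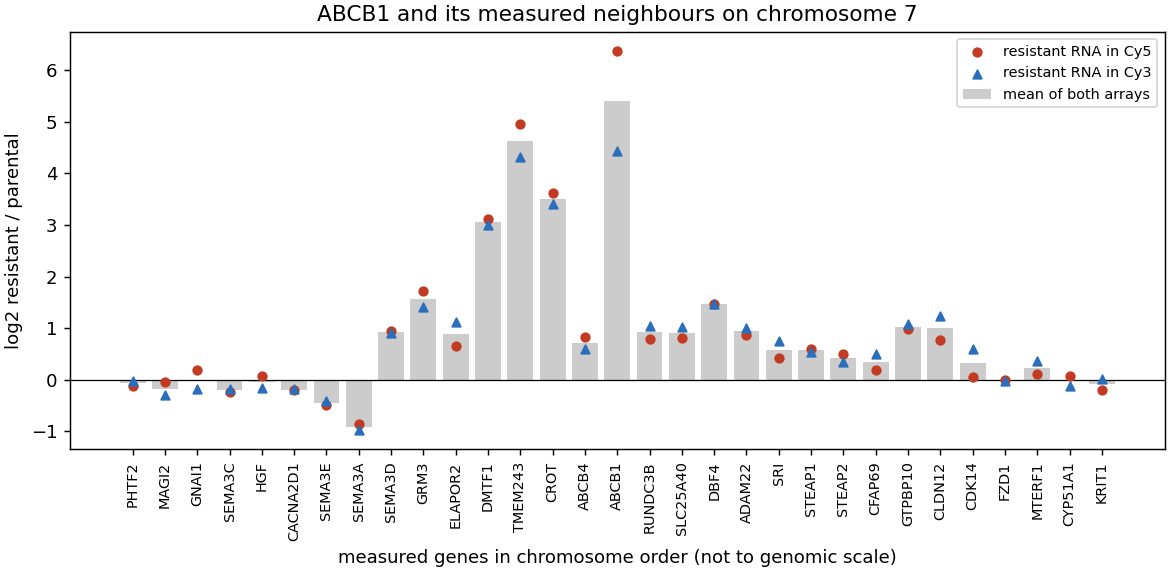
Log2 ratio of resistant over parental RNA (vertical axis) for ABCB1 and the 15 measured genes on each side of it, in chromosome order along the horizontal axis and not to genomic scale. Bars give the mean of both arrays and points the value on each array; ABCB1 itself has 6.37 and 4.44, and TMEM243, CROT and DMTF1 lie above 2.9 on each array.

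The second comparison asked which genes differed at least 2-fold on both arrays. In the resistant cells 66 genes were higher and 201 were lower, together 2.15% of the measured genes. In the main setting, the highest outside chromosome 7 among called genes well above background in both RNAs were SLPI, MMP3 and AK8. SLPI, a secreted inhibitor of serine proteases, had a log2 ratio of 4.18 (18.2-fold). MMP3, the matrix protease stromelysin, stood at 4.04 (16.4-fold) and AK8, an adenylate kinase, at 3.80 (13.9-fold). Next came HLA-DPB1 at 2.59, the trypsin inhibitor SPINK1 at 2.45 and the cell junction gene CGNL1 at 2.29. A second, dimmer probe of CGNL1 gave 0.21. The actin-bundling protein gene LCP1 followed at 2.13 and HLA-DPA1 at 1.96. With the processed signals HLA-DPB1 (4.44) lay above MMP3 (4.25). In the main setting the lowest by the same measure were EBP, a sterol isomerase of cholesterol synthesis, at -3.09 (8.49-fold lower), and BST2, an interferon-induced membrane protein also called tetherin, at -3.07 (8.41-fold lower). The Mediator subunit gene MED18 (-2.89), ADIRF (-2.88), the granzyme gene GZMA (-2.88), HCLS1 (-2.85), the gelatinase gene MMP9 (-2.65), H6PD (-2.64) and the glutaminyl cyclase gene QPCT (-2.63) came next. Smooth-muscle actin ACTG2 stood at -2.50, ZG16B at -2.45 and the collagen VI chain COL6A1 at -2.40.

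In 6 called genes the dimmer RNA was not well above background on either array, and these have only lower bounds. Besides GRM3, OLIG1, a transcription factor gene, was at least 4.13-fold higher and SPRR3, a gene of the cornified envelope, at least 2.16-fold higher. PYCARD, the inflammasome adaptor, was at least 3.31-fold lower, SGCZ at least 2.89-fold lower and SERPINB5 at least 2.76-fold lower.

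The arrays gave the same sign for 73.4% of measured genes, and Pearson's r of their ratios across genes was 0.78, where genes are not independent replicates. A single gene passed 2-fold in opposite directions on the arrays. With the scanner software's processed signals in place of the main normalisation, 231 genes were higher and 381 lower, so that 37.7% of calls were higher against 24.7% in the main setting. Of the 267 called genes, 261 were called in the same direction with those signals. Folds also depended on this choice: of 54 named called genes with a fold that is not a bound, 17 had a fold over 1.5 times larger with the processed signals and 0 had one over 1.5 times smaller. Thus MED18 had a log2 ratio of -4.91 and QPCT of -4.83 with those signals, below EBP at -3.21, and HLA-DPB1 was 21.8-fold and HLA-DPA1 7.85-fold higher. These 17 genes had a median log2 intensity of 7.86 against 10.39 for the other named genes of this kind. Probes did not always agree: of 16 named called genes with over 1 probe, 13 had a probe under 2-fold, as H6PD, whose probes lay between -2.64 and -0.15, and OLIG1, between 0.10 and 2.08.

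**Figure D2:**
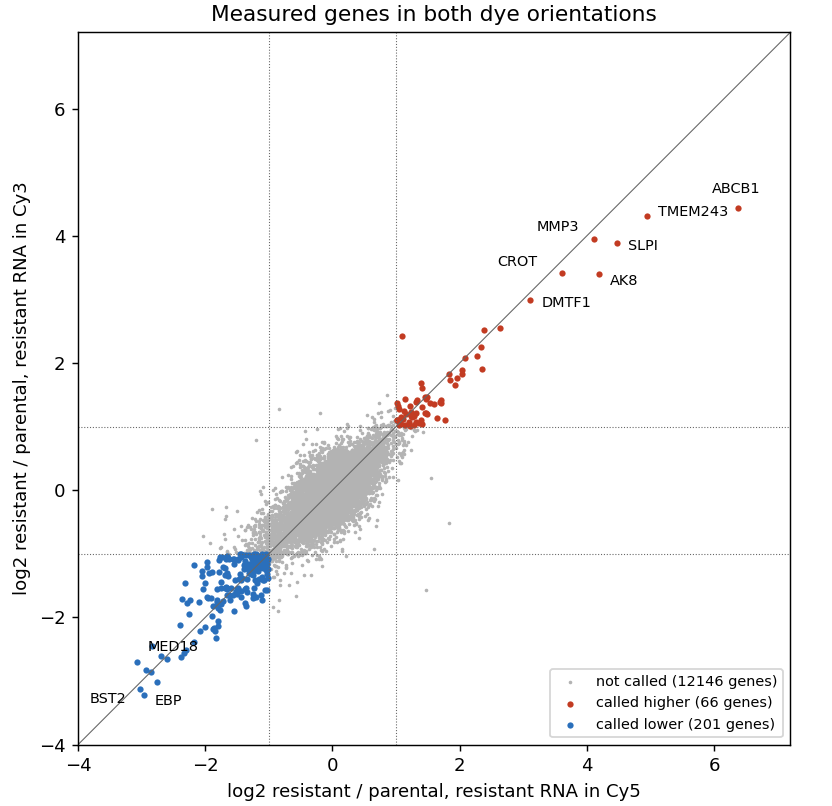
Log2 ratio of resistant over parental RNA for 12413 measured genes on the array with resistant RNA in Cy5 (horizontal) and on the array with resistant RNA in Cy3 (vertical). Red and blue points are the 66 genes called higher and the 201 called lower, dotted lines mark 2-fold and the solid line marks equality; ABCB1 lies off it, at 6.37 and 4.44.

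The third comparison set 31 gene lists, fixed before the data were examined, against 10000 random lists of equal size and matched intensity. Of 30 lists with at least 5 measured members, 4 had a higher and 6 a lower median than random lists. The limit was the outer 0.5% at either end. Lists of genes drawn independently would give 0.3 such lists. Members of a list can vary together, also for technical reasons, so 0.3 is no expectation for these lists. The ribosomal protein list, for example, stood at percentile 98.98 with resistant RNA in Cy5 and 0.01 with resistant RNA in Cy3. The list percentiles describe the 2 RNAs and are not p-values between conditions. Of the 10 lists, 9 stood apart on each array alone.

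Tubulin genes, which encode the subunits of microtubules, had a median log2 ratio of 0.30 (1.23-fold) over 19 measured genes, at percentile 100. Of these, 15 were above 0 and 3 below 0 on both arrays, and none was called in the main setting. The beta-tubulin genes TUBB and TUBB2A had values of 0.91 each. The 3 probes of TUBB lay between 0.20 and 0.91 and the 2 of TUBB2A between 0.79 and 0.91. As tubulin genes are similar in sequence, their probes can cross-hybridise. Genes of the major histocompatibility complex and antigen presentation had a median of 0.26 over 22 genes, at percentile 100. The class II genes HLA-DPB1 (6.03-fold) and HLA-DPA1 (3.90-fold) were called higher, the other 20 members were not called, and 6 were below 0 on both arrays. A second probe gave a log2 ratio of 2.03 for HLA-DPB1 and 0.66 for HLA-DPA1. Cytokines, chemokines and targets of NF-kB had a median of 0.18 over 27 genes, at percentile 99.8. None was called in the main setting, 17 were above 0 on both arrays, and the values of the chemokine gene CCL26 and the receptor gene IL1RL1 were 1.11 and 0.99. With the processed signals these 2 genes were called higher, and the parental signal of IL1RL1 was well above background on 1 array only. That list no longer stood apart when restricted to genes well above background in both RNAs, where its median was 0.16.

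Mesenchymal genes had a median of -0.37 over 28 genes, at percentile 0. MMP9 (6.26-fold), COL6A1 and COL6A3 (4.87-fold), which encode a gelatinase and collagen VI chains, were among 5 members called lower, while MMP3 was 1 of 2 called higher. A second, dimmer probe gave a log2 ratio of -0.64 for COL6A1 and 0.10 for COL6A3. Luminal breast markers had a median of -0.39 over 15 genes, at percentile 0.07. The called members were TFF3 (4.03-fold lower, and 11.8-fold with the processed signals), a secreted trefoil peptide, the transcription factor SPDEF (3.17-fold lower) and keratin KRT19 (3.12-fold lower), and 11 of the 15 were below 0 on both arrays. Integrins and extracellular matrix genes had a median of -0.19 over 38 genes, at percentile 0.11, with ITGA2 (3.55-fold lower) and ITGB4 (2.77-fold lower) called. That list no longer stood apart with the median over probes (-0.12), without the filter on dim probes (-0.08) or without genes of the chromosome regions described below (-0.15). Growth factors and their receptors had a median of -0.18 over 48 genes, at percentile 0.06. IGFBP4 (2.96-fold), BMP2 (2.66-fold) and IGF2 (2.33-fold) were lower, and FGF1 was 2.16-fold higher. The weakest probe lay at -0.27 for TFF3, -0.38 for ITGA2, -0.11 for IGF2 and 0.53 for FGF1.

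Interferon response genes had a median of -0.23 over 33 genes, at percentile 0.2. BST2 was the 1 member called, and the list was not apart on the array with resistant RNA in Cy5 alone (median -0.10, percentile 12.2). It was also not apart in the series table (-0.18), without the filter on dim probes (-0.08) or by its mean (-0.26). Markers of endothelial cells had a median of -0.49 over 8 measured genes, at percentile 0.06, with the adhesion molecule PECAM1 2.63-fold lower. Without the filter on dim probes the median was -0.05 and the list was not apart.

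The other lists with a percentile did not stand apart from random lists, though some held called genes. Among stress genes DDIT3 (2.34-fold), ATF3 (2.31-fold) and PPP1R15A (2.09-fold) were higher and DDIT4 was 2.17-fold lower, with a list median of 0.01 over 25 genes. The heat shock gene HSPA6 (2.54-fold), the haem-degrading enzyme HMOX1 (2.32-fold), the drug-metabolising enzyme CYP1A1 (2.54-fold), the peptide hormone ADM (2.34-fold) and GADD45G (2.26-fold) were also higher. The aldo-keto reductases AKR1C1 (2.64-fold) and AKR1C3 (2.38-fold), the apoptosome gene APAF1 (2.22-fold) and the Notch ligand JAG1 (2.26-fold) were lower. So were ALDOC (2.10-fold), CLDN7 (2.45-fold), PKP2 (2.17-fold) and the cancer-testis antigen gene SSX1 (2.61-fold, and 17.9-fold with the processed signals). The resistant signal of SSX1 was well above background on 1 array only. In the main setting no member was called among 32 microtubule-associated proteins (median 0.08), 34 genes of mitosis and the spindle checkpoint (0.07), 25 DNA replication genes (0.08), 11 uptake transporters (-0.05), 59 ribosomal proteins (-0.03, of opposite sign on the arrays) or 24 housekeeping genes (-0.01). The mean and the median differed in sign for the housekeeping genes (mean 0.01) and for the p53 and growth arrest genes (median -0.04, mean 0.03). Named calls that were lost in a setting were those of ATF3, IGF2, FGF1 and SERPINB5 with the median over probes, of ADM with the processed signals, the series table or median centring, and of GADD45G with median centring. Some markers of other cell types were measured in both RNAs. Of 22 leukocyte markers, 11 were well above background in the parental and 12 in the resistant RNA, and LCP1 was the 1 called. Of 14 melanocyte markers 7 were well above background in each RNA and none was called. MITF had a value of 0.90, but its 4 probes lay between -0.37 and 1.02. Of 18 hepatocyte and colon markers 4 were well above background in each RNA, too few for a percentile, with APOA1 4.09-fold lower (9.98-fold with the processed signals). Of all 16413 genes, 12055 were well above background in both RNAs, a larger share than of these leukocyte, melanocyte, or hepatocyte and colon markers. Whether the marker counts reflect other cells was not tested.

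**Figure D3:**
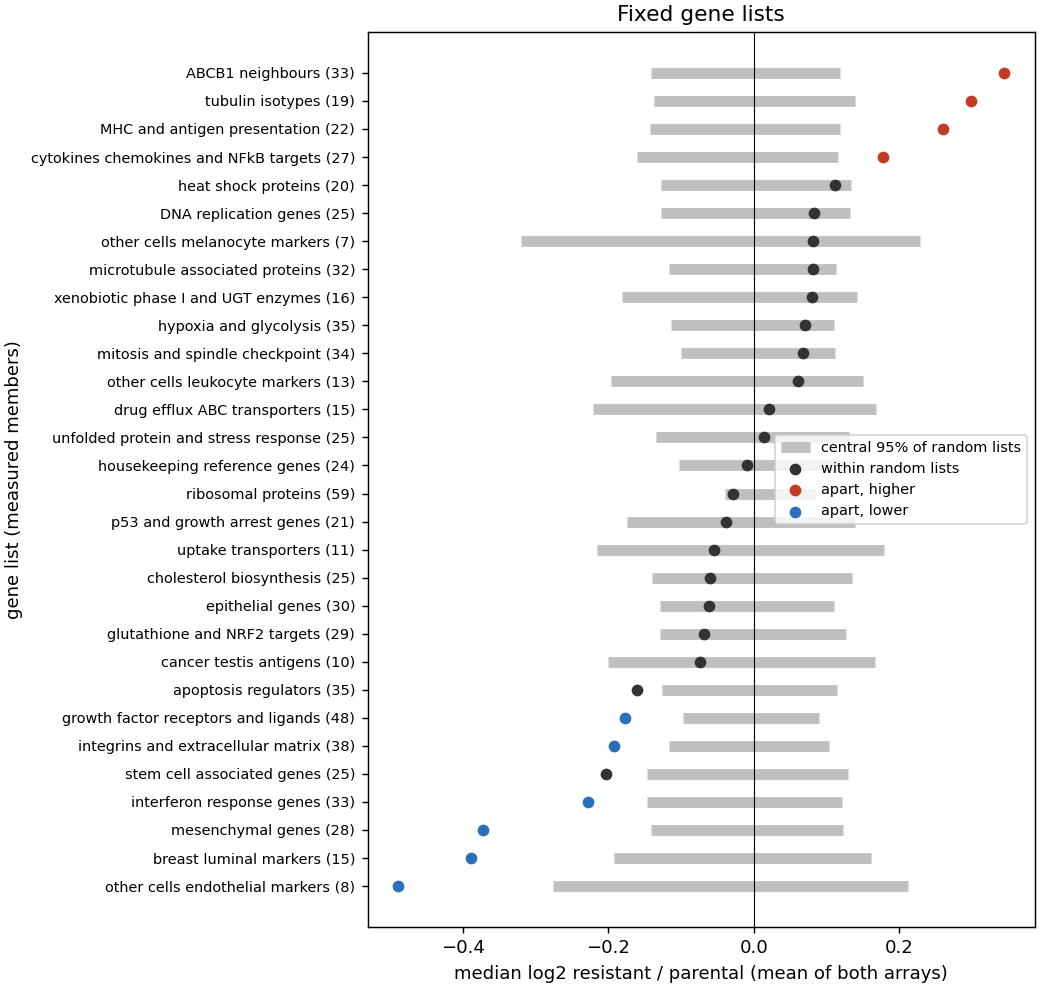
Median log2 ratio of resistant over parental RNA (horizontal axis, mean of both arrays) for the 30 gene lists with at least 5 measured members, whose number stands in parentheses. Grey bars span the central 95% of random lists matched on size and intensity; the ABCB1 neighbours (0.34) lie farthest to the right and the endothelial markers (-0.49) farthest to the left.

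The fourth comparison asked whether neighbouring genes differed together, by the running median of 15 neighbouring measured genes against 1000 shuffles of gene order. Of 12084 windows, 203 were above the upper limit of 0.39 and 5 below the lower limit of -0.54, and 150 of these 208 lay on chromosome 20. The highest window median, 0.94, belonged to the region around ABCB1. On chromosome 20, 3 regions of 115, 80 and 21 measured genes had median log2 ratios of 0.50, 0.44 and 0.32, which are 1.42-, 1.36- and 1.25-fold. In the first of these, from ABHD12 to WFDC10B, 93 of 115 genes were above 0 on both arrays, 4 were called higher and 1 was called lower. Chromosome 20 as a whole had a median of 0.23 over 346 genes, with 7 called higher and 6 called lower, while the medians of the other chromosomes lay between -0.14 and 0.08. Chromosome 14 held 2 regions, EIF2B2 to ZC3H14 with a median of 0.40 over 38 genes and KLC1 to CRIP2 with 0.39 over 19. A region of zinc finger genes on chromosome 19, from ZNF682 to POP4, had a median of -0.66 over 18 genes, and 4 of them were called lower. Smaller regions lay on chromosomes 4 (0.38, 24 genes), 6 (0.33, 24 genes) and 9 (-0.55, 15 genes). The region on chromosome 4 was found with none of 4 further sets of shuffles and the others with all 4. The regions on chromosomes 7, 9 and 19 and the 2 longer ones on chromosome 20 were found on each array alone. The region on chromosome 6 was found on neither array alone, and the remaining regions on 1 array. Region ends depend on the window, and the genes at them were named after their values were seen.

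**Figure D4:**
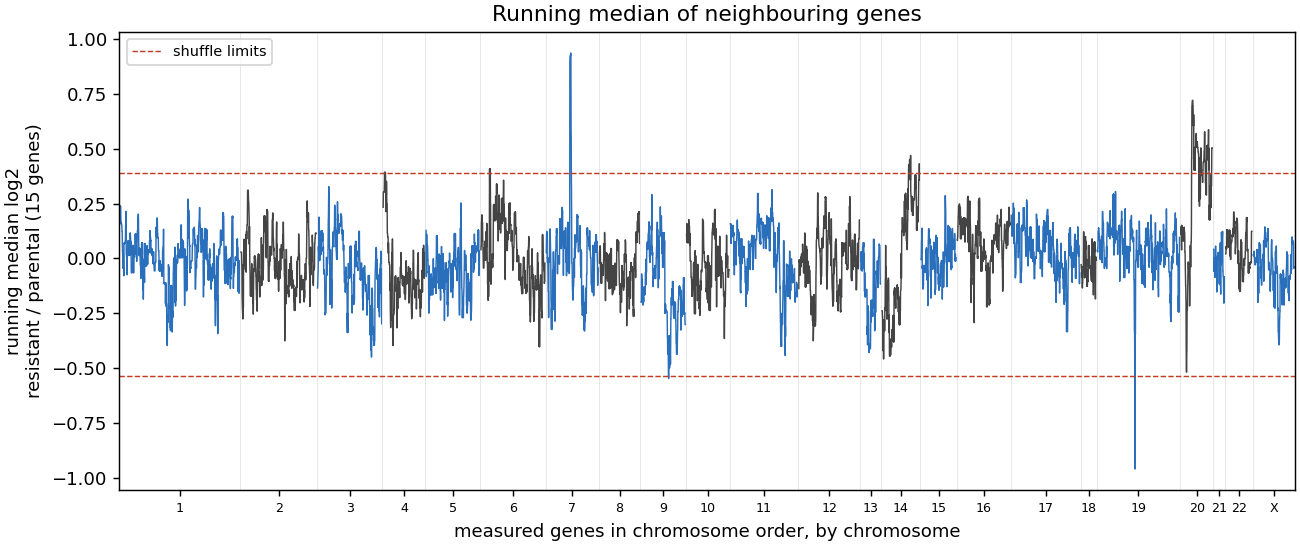
Running median of the log2 ratio of resistant over parental RNA (vertical axis) over 15 neighbouring measured genes, in gene order along chromosomes 1 to X, which alternate in colour. Dashed lines are the limits from shuffled gene order, 0.39 and -0.54; the peaks on chromosomes 7 and 20 reach 0.94 and 0.72 and the trough on chromosome 19 reaches -0.96.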

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

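The tests of the ABCB1 difference in this part were chosen after the result was seen. Probes with no gene symbol were outside the comparisons. Among 9315 such probes that were measured, 33 were higher and 61 were lower by at least 2-fold on both arrays in the resistant cells, 1.01% of them, which marked them for a closer look. By mean ratio in the main setting, the highest, the probe for BC035377, had a log2 ratio of 4.85, and the next, for BE165955, had 3.76. The lowest, for CR616003, had -2.62. These 3 were picked by size, and the genes behind them were not identified here.

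The ABCB1 ratio differed by 1.93 on the log2 scale between the arrays and was smaller where the resistant RNA was in Cy3. Scatter like that of measured genes in general is argued against, as 4 others among the 12413 measured genes differed by as much. Of the measured genes, 82.3% lay within 1.5-fold on both arrays. The count therefore does not cover scatter at ratios as large as that of ABCB1. Cy3 light counted in the Cy5 channel would need 3.39% of the Cy3 signal at ABCB1, but genes called lower, which would show it on the other array, had a median of -0.8% (bootstrap 95% interval over genes -1.55 to 0.41). A candidate explanation that stays open is resistant RNA in the parental labelling of 1 array: ABCB1 would need 3.43%, and the other 65 genes called higher had a median of 2.4% (1.12 to 4.78), although 5 of the 6 other genes called higher with a log2 ratio of at least 3 where the resistant RNA was in Cy5 needed less, from 0.72% for MMP3 through DMTF1, CROT and TMEM243 to 2.4% for SLPI, and AK8 needed 4.22%. The labels do not say outright that both arrays used the same extracts, so a difference between extracts also stays open and untested, as does a dye effect of the single ABCB1 probe itself. No biological explanation was tested.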

How the results depend on the processing

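Each setting changed 1 choice, except the software's processed signals and the series table, which replace background correction and normalisation together. The 2-fold calls (66 higher, 201 lower, 267 in all) moved to 231, 381 and 612 with the software's processed signals and to 231, 386 and 617 with the series table. Genes called with the processed signals and not in the main setting had a median log2 intensity of 6.71 against 10.48 for measured genes. The cause of the gain was not tested. Changing the background step alone gave 311 calls without subtraction and 372 with an offset of 10. With an offset of 10, added after the data were seen, 106 genes were higher. At 1.5-fold 282 were higher and 642 lower (924), and at 4-fold 12 and 15 (27), as the rule itself implies. With each array alone the counts ranged from 99 to 110 higher, 274 to 365 lower and 373 to 475 in all, which is fewer conditions to meet. Windows outside the limits numbered 208, against 136 with processed signals, 134 to 150 with each array alone and 470 with 31 genes per window. For the window counts the cause was not tested. Other settings kept all of these counts within 1.5 times, and r between orientations stayed within 0.05 of 0.78. The ABCB1 log2 ratio lay between 4.44 and 6.37 over all settings.

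The number of lists apart was 8 to 12 in all settings. Tubulins, antigen presentation, mesenchymal, luminal and growth factor lists stood apart in all 13 settings. The list of ABCB1 neighbours reversed, to -0.35, without genes of the chromosome regions, which leaves 5 members by construction. Apoptosis regulators and stem cell genes, just inside the limits, passed them in 4 and 5 settings, and the heat shock, ribosomal, efflux transporter and cholesterol lists in 1 each. Of 60 named called genes, 54 were called in the same direction in all 8 settings that give single-gene values, and none reversed. No paired analysis was possible because the result comes from no test. Leaving out saturated spots was not run, since there were none. For 6 called genes the dimmer RNA's signal over background allowed only a lower bound.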

Other observations

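The test of ribosomal protein genes and that of extra chromosome copies were chosen after the results were seen, and those of a trend and of a few genes on chromosome 20 before, except for the percentile among random lists. Zinc finger genes of the lowered region on chromosome 19 had a median log2 ratio of -0.94 over 16 measured genes in the resistant cells, with 14 below 0 on both arrays and 4 called lower. The other 152 ZNF genes of chromosome 19 had a median of 0.01, and the 166 on other chromosomes 0.01. As the region was picked by its low running median in the same values, this contrast among ZNF genes is no separate support for it. Members of this family are similar in sequence, so their probes are not independent. Clustered histone genes on chromosome 6 had a median of -0.02 over 47 genes and were of opposite sign on the arrays (-0.10 and 0.16), and 10 on other chromosomes had 0.39.

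Chromosome 20 did not differ evenly along its length: the 113 measured genes before ABHD12 had a median log2 ratio of 0.01, and the 233 from ABHD12 on had 0.44 (1.36-fold), with 84.5% above 0. This split was set after the values were seen, and no test of change points was run. A few strongly changed genes are argued against as the source, since 73.7% of all 346 genes of the chromosome were above 0, against 49.3% elsewhere. A dye or intensity trend is argued against by percentile 100 among random lists matched on intensity on each array alone, although the lowest excess over other genes of similar intensity on the same array, 0.0865 among the dimmest genes, did not reach the bound of 0.116 set before the test. Extra copies of part of the chromosome in the resistant cells remain a hypothesis. The value that bears on it is the median of 0.44 from ABHD12 on, as the 0.2313 over the whole chromosome also includes the part at 0.01. Such copies predict genes higher together, but a shared change in regulation predicts the same, and DNA was not analysed here.

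Ribosomal protein genes had a median log2 ratio of 0.14 with resistant RNA in Cy5 and -0.208 with resistant RNA in Cy3. An intensity trend left after normalisation is argued against, since the median deviation between orientations, 0.17, lay at percentile 100 of random lists matched on intensity, with 48 of 59 genes above 0. A difference in level between the cells has the same sign in both orientations and cancels in that deviation, so by construction it does not account for it, and the mean over both arrays had a median of -0.03, at percentile 4.64. A dye effect tied to the probes or the RNAs themselves was not tested.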
